A study of Drosophila melanogaster with 4 samples.

How the data were processed

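ChIP-seq was done on Kc167 cells fixed with 1.8% formaldehyde for 10 min, sonicated, and incubated with the antibody for 15 h, per the labels' protocols. The series has 2 input and 2 ChIP libraries, and the labels number the replicates in each group but do not say whether they came from separate cultures, so the spread between replicates may be technical. Bowtie 0.12.7 was used, per the submitters' processing notes, which give no settings. Positions refer to FlyBase release 5, per the file headers. The region caller, its threshold, its control and the way the replicates were combined are not given in the sources used here. The authors called regions in each ChIP replicate and deposited 1 further list for the replicate set. It was taken as their combined list and printed as their value with no SD. A mean ± SD is over the 2 replicate lists.

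Each list gives the position of a region, a type (enriched or depleted) and a score. The authors deposited the score without naming its scale, and it was read as a log2 value for the following reasons. It is above 0 in every enriched region and below 0 in every depleted one. Among all scores of a list, 97 in the combined list, 108 in replicate 1 and 90 in replicate 2 had another score exactly 1 higher (tolerance 1e-10), while 0 had one higher by the common or the natural logarithm of 2. Relative to the most frequent score of the list, 2 to the power of the score difference was a ratio of whole numbers with a denominator of at most 3000 (tolerance 1e-11) for 84.4%, 97.9% and 86.7% of the scores. How often scores of another form would meet that bound is not given here. These values fit a log2 of a ratio of whole numbers times a constant of each list, although the remaining scores of each list did not meet that bound and the form was not settled for them. What the ratio compares is not given in the sources used here, no read counts were derived from it, and the score was used only to describe, rank or filter regions within a list and to correlate matched regions of the replicates. Sequencing depth is unknown, and no interval or limit that needs counts is given.

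Enriched regions were used as deposited, and regions typed as depleted were left out of the main values. Regions were shared when they overlapped by at least 1 bp. Overlap on the 6 arms was tested against 1000 rotations of replicate 2 around each arm, which keep the widths and the spacing of regions (one-sided). Scores, widths and the covered percent of 1 Mb windows were compared by two-sided permutation tests with 100000 resamples (10000 under other settings), and shares by two-sided Fisher's exact tests. Benjamini-Hochberg adjustment was over 7 comparisons within a list, or over the 5 large arms. The interval of the difference between X and the autosome arms is a 95% bootstrap interval over windows with 10000 resamples. Arm ends were compared with 1000 rotations, and the spacing of regions with 1000 random placements that kept the number of regions and the total gap length of each arm. A last window shorter than 50% of the window size was left out. Rotation and permutation tests over positions measure departure from chance placement and do not cover the error between replicates. The comparisons of overlap, and of score with width and sharing, were set before the data were examined. Those of windows, arms, scaffolds, arm ends, the 10 score groups and spacing were added afterwards. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

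The rule for naming, set before the data were examined, was to name genes with a start site in the highest-scoring combined regions, or, with a reference of another build, to give no gene and to list by position the 10 combined regions with the highest score that both replicates overlap. The gene table supplied for the species is of release 6 and coordinates were not converted, so the second form applied. For the same reason the planned tests of transcription start sites, gene features, 22 gene lists, regions along whole genes, and X against autosomal genes were not run, and X was compared with the autosome arms by windows and regions instead. Alternatives were merging of nearby regions, a stricter threshold by score or width, a reciprocal overlap of 50%, each replicate list in place of the combined one, and inclusion of depleted regions.

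The tests were first run on data with known answers, made from the replicate 1 list. Of its 4708 enriched regions on the arms, 79.7% were kept in a second list with slightly moved positions, and 79.9% were measured as shared. Of 100 pairs of lists placed at random, 7 had a rotation p at or under 0.05. These simulated lists lacked the crowding of the real regions, so they do not show how the rotation p behaves for crowded ones. Of 100 random score sets of 128 regions, 6 had a permutation p at or under 0.05, and a planted shift of 0.3 was called in 98 of 100. Of 100 window sets with no difference, 5 were called, while a planted difference of 3 percentage points between 22 of 97 autosomal windows and the remaining ones was called in 74 and one of 5 points in 98.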

Results

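The study mapped RNA polymerase II whose largest subunit carries phosphate on serine 5 of the heptad repeats in its C-terminal tail, the form of the enzyme associated with the start of transcription and the first part of the transcribed unit. Chromatin came from Kc167 cells, a female cell line derived from Drosophila melanogaster embryos, and was precipitated with a rabbit polyclonal antibody against the phosphorylated repeat. The series held 2 ChIP libraries and 2 libraries of input DNA. Values came from a list of called regions for each ChIP replicate and from 1 list that the authors made for the replicate set, called the combined list here. Region lists of the input libraries are not analysed here, so no background level measured in the same way can be given. The lists gave no read counts and the sequencing depth is unknown. All positions are those of FlyBase release 5.

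Regions rich in the Ser5-phosphorylated polymerase covered about 15% of the 6 chromosome arms 2L, 2R, 3L, 3R, X and 4. The replicates held 4874 and 4822 enriched regions, a mean of 4848 ± 36.8 (SD, n = 2), and these covered 15.0% ± 0.202 (SD, n = 2) of the arm bases. The combined list held 5074 regions and covered 16.5% of the arms, or 20.5 Mb over all sequences. Most regions were short. Their median width was 2.64 kb in replicate 1, 2.73 kb in replicate 2 and 2.73 kb in the combined list, and 58.7%, 56.2% and 55.1% of the regions were narrower than 3 kb. Regions of at least 10 kb made up 4.54% ± 0.297 (SD, n = 2) of the replicate regions but 16.8% ± 0.744 (SD, n = 2) of their bases.

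The same places were called in both replicates. On the 6 arms, 4593 of 4708 regions of replicate 1 (97.6%) overlapped a region of replicate 2 by at least 1 bp, and 4506 of 4652 regions of replicate 2 (96.9%) overlapped a region of replicate 1. Bases in both lists made up 0.923 of the bases in either (Jaccard index). When the regions of replicate 2 were rotated around each arm 1000 times, at most 36.5% of the replicate 1 regions were hit and the Jaccard index reached at most 0.121. Both one-sided p-values were 0.001, the smallest that 1000 rotations can give. The boundaries were also close: among 4325 regions matched 1 to 1 over all sequences, the median difference was 32 bp at the start and 32 bp at the end, and no pair had both boundaries or the score identical.

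The authors' score was above 0 in every enriched region and was read as a log2 ratio, on which a difference of 1 is a 2-fold difference. It was compared within each list, and between lists it was only correlated or set side by side. Each list may have its own constant, so a gap in score between lists was not interpreted. Over the 4325 matched pairs the scores correlated across regions with Pearson's r of 0.988 and Spearman's rho of 0.988. Regions are not independent replicates, so no p-value is attached to this correlation. The regions without a partner in the other replicate were weaker on average. In replicate 1, 128 unshared regions averaged a score of 0.66 against 1.54 in 4746 shared regions, a difference of 0.88. In replicate 2, 163 unshared regions averaged 0.61 against 1.56 in 4659 shared regions, a difference of 0.95. Both differences had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. The groups were set by whether the other replicate called the region, and matched scores go closely together. A lower score of the unshared regions would therefore largely follow from that choice. Single unshared regions scored up to 3.91 in replicate 1 and 4.75 in replicate 2. When sharing needed a reciprocal overlap of 50%, the differences were 0.58 and 0.78.

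**Figure D1:**
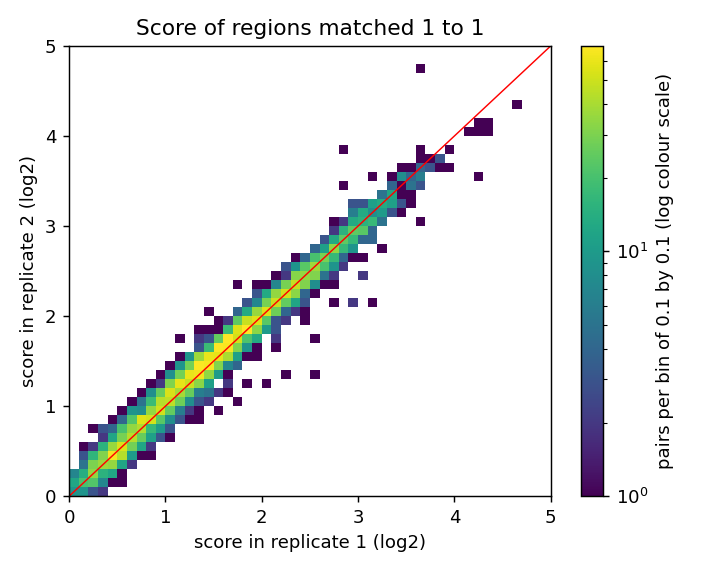
Score in replicate 2 (y axis, log2) against score in replicate 1 (x axis, log2) for 4325 regions matched 1 to 1, with the number of pairs per bin as a log colour scale and a red line where both are equal. The scores rise together with Spearman's rho of 0.988, and a few pairs lie well away from the rest.

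Scores of single regions are given as each list has them. The combined region with the highest score among those found in both replicates lay on 2R at 13029770 to 13034598, with a combined score of 4.49 and scores of 4.63 and 4.36 in the lists of replicates 1 and 2. Next came a region of the unplaced sequence U at 2929154 to 2931468, whose combined score was 4.31 and whose replicate scores were 3.70 and 4.78. On 2L, 3 regions followed the same rule: 21213770 to 21216298 with a combined score of 4.29 and replicate scores of 4.38 and 4.20, 13214698 to 13217354 with 4.20 and replicate scores of 4.34 and 4.07, and 13243228 to 13246070 with 4.17 and replicate scores of 4.24 and 4.09. On 3R, 19683908 to 19686492 had a combined score of 4.19 and replicate scores of 4.26 and 4.13, and 3918530 to 3921022 had 3.82 and replicate scores of 3.82 and 3.80. On 3L, 3089686 to 3092266 had 4.08 and replicate scores of 4.13 and 4.05, and 1462484 to 1465154 had 3.86 and replicate scores of 3.91 and 3.83. The other region of U, at 8031868 to 8034530, had a combined score of 3.92 and replicate scores of 4.21 and 3.55. Scores above 4.49 occurred in the combined list only in regions missing from at least 1 replicate list. All but the 2R region were between 2.32 and 2.84 kb wide. No gene is named, since the gene table supplied for the species belongs to release 6.

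The widest region of the combined list lay on 3R at 1096068 to 1135102, spanned 39.0 kb and scored 1.47, and each replicate list held it as a single region of 38.9 and 39.1 kb. The next, on 3R at 7414148 to 7450476, spanned 36.3 kb with a score of 1.76 and was again a single region in each replicate. The 28.4 kb region on 2R at 14012020 to 14040438 scored 2.14 and was divided into 3 regions in each replicate. The 27.7 kb region on X at 8767090 to 8794788 scored 1.37 and was divided into 4 in replicate 1 and 5 in replicate 2. These regions were picked for their width after the values were seen.

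Across regions, width rose with score and then fell among the highest scores. Spearman's rho of score and width was 0.554 in the combined list, 0.580 in replicate 1 and 0.589 in replicate 2, across regions, which are not independent replicates. When the combined regions were ranked by score and divided into 10 groups of equal size, the median width rose from 1.77 kb in group 1 to 4.32 kb in group 8 and was 2.89 kb in group 10. The mean width of group 10 minus that of group 9 was -1.45 kb in the combined list, -1.12 kb in replicate 1 and -0.985 kb in replicate 2, each with a two-sided permutation p of 1e-05. Regions narrower than 3 kb made up 51.8% of group 10 and 32.7% of group 9 in the combined list. This comparison was chosen after the values were seen.

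**Figure D2:**
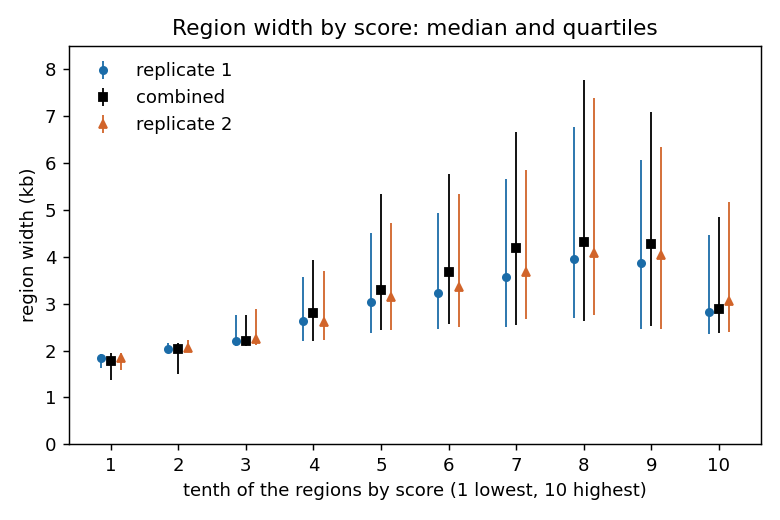
Region width in kb (y axis; points are medians and bars run from the lower to the upper quartile) in 10 groups of equal size ordered by score (x axis, 1 lowest), for each replicate and the combined list. The combined median is highest in group 8, at 4.32 kb, and is 2.89 kb in group 10.

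The labels state that the cells are female, so the X chromosome was set against the autosome arms. Enriched regions covered 14.6% ± 0.234 (SD, n = 2) of X and 15.1% ± 0.196 (SD, n = 2) of 2L, 2R, 3L and 3R together, and X was the less covered in both replicates (14.4% against 15.0%, and 14.8% against 15.3%). In windows of 1 Mb, the combined list covered on average 16.5% of 22 X windows and 16.6% of 97 autosomal windows, a difference of -0.146 percentage points with a 95% bootstrap interval over windows from -2.44 to 2.15 and a permutation p of 0.909. The replicates gave differences of -0.306 and -0.253 points with permutation p-values of 0.795 and 0.832, and leaving out the centromeric 2 Mb turned the combined difference to 0.292 points with a permutation p of 0.832. Windows of 500 kb gave -0.506 points with a permutation p of 0.675, but they take in a sparsely covered end of X that the 1 Mb windows leave out, and inside the 1 Mb windows they gave -0.196 points with a permutation p of 0.871. Scores on X averaged 0.015 above those of the autosome arms in the combined list (adjusted p = 0.898, permutation test with Benjamini-Hochberg adjustment over 7 comparisons). Of the X regions, 53 of 878 were at least 10 kb wide, against 247 of 3898 on the autosome arms (two-sided Fisher's exact test, p = 0.817). None of these tests of windows, scores and wide regions passed its threshold. Windows and regions stand for positions in the genome and not for replicates, so these p-values do not cover the error between cultures.

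Among the arms, 2R was the most densely occupied. It held 47.1 ± 0.535 regions per Mb (SD, n = 2), against 36.0 ± 0.277 on 2L, 38.1 on 3L (the same count in both replicates), 36.6 ± 0.203 on 3R and 37.9 ± 0.662 on X. Enriched regions covered 17.3% ± 0.221 of 2R, 13.7% ± 0.162 of 2L, 14.4% ± 0.212 of 3L and 15.3% ± 0.192 of 3R (SD, n = 2). The gap between 2R and each of the other arms exceeded the replicate SD. In 1 Mb windows, however, 2R exceeded the other large arms by 3.12 percentage points with a permutation p of 0.0163, and after adjustment over 5 arms the p was 0.0817, with 0.0882 and 0.0902 in the replicates, so the difference did not stand out from the variation along the arms. The small chromosome 4 was 13.0% covered ± 0.111 (SD, n = 2), and its region scores did not differ detectably from those of the 5 large arms (difference -0.12 in the combined list, adjusted permutation p = 0.534, and -0.06 and -0.04 in the replicates).

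**Figure D3:**
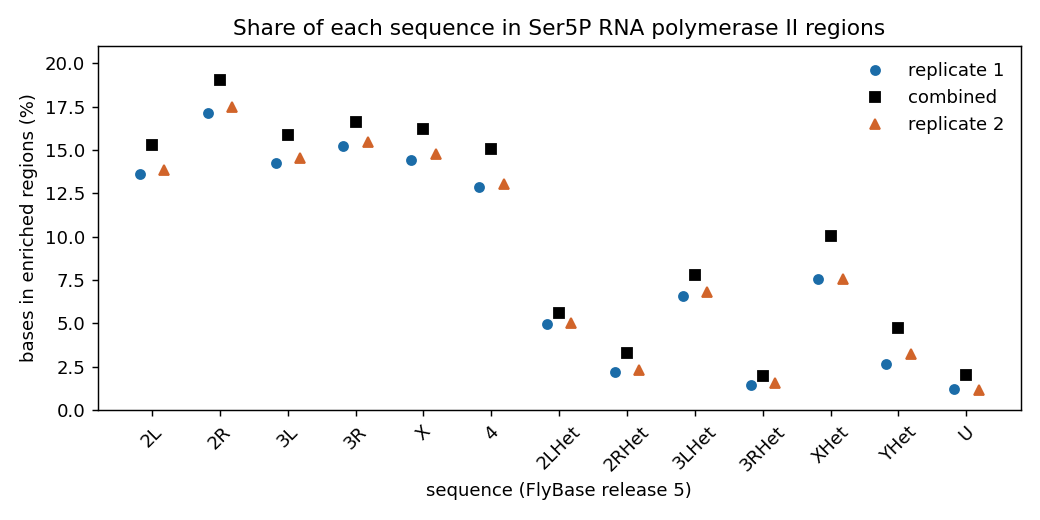
Share of bases in enriched regions (y axis, percent) for each chromosome arm, heterochromatin scaffold and the unplaced sequence U (x axis), with 1 point per list. The 6 arms lie between 12.9% and 19.0% in all 3 lists, and the scaffolds and U between 1.18% and 10.0%.

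Heterochromatin scaffolds, which hold assembled parts of the repeat-rich DNA around the centromeres and of the Y chromosome, were sparsely covered by enriched regions. Enriched regions covered 3.52% ± 0.113 (SD, n = 2) of the 6 scaffolds together, so the arms were covered 4.32 times as densely in replicate 1 and 4.21 times in replicate 2. The scaffolds differed from each other by more than the replicate SD, which does not cover how far a few regions can rank them. In each replicate XHet held 7 regions, 2LHet 5 and 3RHet 12. In replicates 1 and 2, YHet held 4 and 5, 2RHet 24 and 25, and 3LHet 58 and 59. XHet was 7.57% covered ± 0.017, 3LHet 6.70% ± 0.188, 2LHet 4.98% ± 0.059, YHet 2.93% ± 0.398, 2RHet 2.25% ± 0.060 and 3RHet 1.48% ± 0.085 (SD, n = 2). In the combined list YHet was 4.73% covered. Regions on the 6 scaffolds together scored 0.33 lower than those on the arms in the combined list (adjusted permutation p = 3.5e-05), and 0.31 and 0.30 lower in the replicates. This did not hold in each scaffold. In the combined list the median score was 0.56 in XHet, 0.70 in 2RHet and 0.88 in 3LHet, against 1.37 on the arms. It was 1.30 in 2LHet and 1.45 in both 3RHet and YHet. Regions on the scaffolds together averaged 2.83 kb in width in the combined list against 4.12 kb on the arms (adjusted permutation p = 0.000117). Unplaced sequence U was 1.18% covered ± 0.003 (SD, n = 2), with 56 and 57 regions in the replicates, and 2.01% covered with 98 regions in the combined list. Its regions scored 0.52 higher than those on the arms in the combined list (adjusted permutation p = 3.5e-05), and 0.43 and 0.45 higher in the replicates. With only the combined regions found in both replicates the difference was 0.33 (permutation p = 0.0065). The other set of unplaced sequence, Uextra, spans 29 Mb and held 0 regions in all 3 lists. Whether reads were aligned to it is not given in the sources used here. All these percents are of the full length of a sequence. How much of the scaffolds, U and Uextra could take up aligned reads was not measured. Little polymerase there cannot be told apart from bases on which reads could not be placed.

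Along the arms, occupancy varied far more between windows of 1 Mb than between the replicates. The median of 119 windows was 14.9%, and the replicate SD within a window had a median of 0.231 points and reached at most 1.10. The least covered window was 2L 14 to 15 Mb at 2.54% ± 0.028, followed by 2L 17 to 18 Mb at 3.79% ± 0.130 (SD, n = 2). The most covered were 3R 19 to 20 Mb at 29.2% ± 0.084, 3R 5 to 6 Mb at 25.9% ± 0.298 and 2R 3 to 4 Mb at 25.3% ± 1.10 (SD, n = 2). The centromeric 2 Mb of the 5 large arms were 14.2% covered in the combined list, against a mean of 16.7% after rotation of the regions around the arms (two-sided circular-shift permutation p = 0.154, 1000 rotations). In the centromeric 1 Mb the value was 11.8% (two-sided circular-shift permutation p = 0.038), a size chosen after the values were seen. The telomeric 2 Mb were 19.4% covered (two-sided circular-shift permutation p = 0.0939) and the telomeric 1 Mb 19.1% (two-sided circular-shift permutation p = 0.326).

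**Figure D4:**
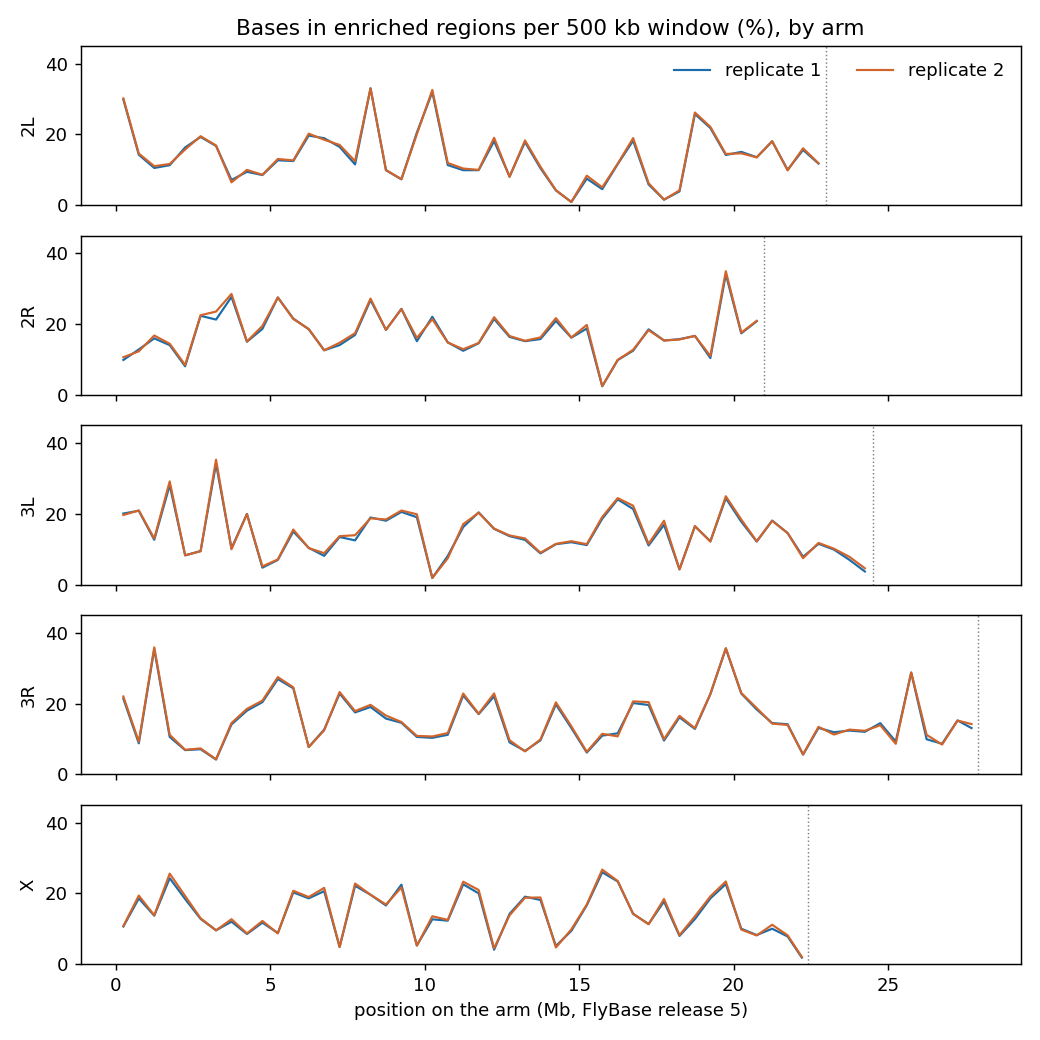
Share of bases in enriched regions (y axis, percent) in windows of 500 kb along the 5 large arms (x axis, position in Mb), 1 line per replicate, with a dotted line at the end of the last window. The lines of the replicates nearly coincide, and windows run from 0.885% to 35.9%.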

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

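Besides the enriched regions, the lists hold regions typed as depleted, which the comparisons above do not use: 67 in the combined list, 17 in replicate 1 and 16 in replicate 2. They drew attention as a signal in data outside the main measurement. The tests on the depleted regions and on the high-scoring regions missing from a replicate list were chosen after the result was seen, while those on combined regions absent from both replicate lists were set before.

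All depleted regions lay on the 5 large arms and were between 1257 and 1873 bp wide. Their lowest score in the 3 lists was -0.29, but what level a score of 0 stands for is not given in the sources used here, so a strong loss of the polymerase cannot be told apart from a slight one. Of the 67 combined depleted regions, 53.7% (36 regions) overlapped a region that a replicate list types as enriched, and 14 overlapped enriched regions of both replicates. A further count gave 23 that overlapped a depleted region of a replicate and 17 that overlapped no replicate region. In 1000 rotations the enriched share reached at most 40.3%. The combined list was taken to rest on the same libraries as the replicate lists, so overlap above the rotations does not bear on what sets the type. The overlapping enriched regions had median scores of 0.08 in replicate 1 and 0.13 in replicate 2, and reached at most 0.31 and 0.29. In the other direction, 16 of the 17 depleted regions of replicate 1 and 14 of the 16 of replicate 2 overlapped a depleted combined region. Between the replicates the type was less stable. Of these depleted regions, 6 of the 17 of replicate 1 and 6 of the 16 of replicate 2 overlapped an enriched region of the other replicate. In all 3 lists the type went with the sign of the score in every region. A score near 0 whose sign differs between lists is a candidate explanation for the combined depleted regions that a replicate list types as enriched. No biological explanation was tested.

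The combined list also holds 455 regions that overlap no enriched region of either replicate. Of these, 83.5% scored below the median of the regions found in both replicates. Their mean score of 0.75 lay 0.79 below the 1.53 of those regions (permutation p = 1e-05). The groups were set by whether a region was called in the replicates, so a lower score would largely follow from that choice. Weaker regions that pass only in the combined call remain a candidate explanation, which this test cannot decide. A lower minimum width in the combined call may also play a part. Of the 455, 60.4% were narrower than 1303 bp, the narrowest replicate region. That share lies between the bounds set for and against the explanation by width, so the part it plays cannot be told apart. No biological explanation was tested.

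Among combined regions scoring over 3, 20 were missing from at least 1 replicate list and 203 were in both. The highest score of the combined list, 5.07 on 3R at 8315928 to 8317994, was found in replicate 2 only, and a region at 8307958 to 8310034 on the same arm with 4.00 in replicate 1 only. Of the 20, 50% (10 regions) lay on unplaced or heterochromatin sequence, against 3.94% of the 203 (Fisher's exact p = 8.31e-08). A score that another region of the list holds exactly was found in 60% (12 regions), against 0 of the 203 (Fisher's exact p = 5.39e-15). These 12 regions were tied only with each other: 7 at 3.105, 3 at 3.243 and 2 at 3.368. Tied regions count together, so they are not independent and the second p overstates the evidence. Sequence held in several copies and ratios of small numbers, which fall on few values, are both candidate explanations, and they may act together. No biological explanation was tested.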

How the results depend on the processing

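The 70 values under other settings covered 17 results, and 58 either kept the direction and side of the threshold of a test, moved by less than the spread, or, for counts, stayed within 1.5 times. Within that bound, the 5074 combined regions became 4278 when those closer than 1 kb were merged, and the 211 long gaps became 302 under the stricter threshold by score. The difference between X and autosomal windows changed sign, to 0.292 points (permutation p = 0.832) without the centromeric 2 Mb, from -0.146 points (permutation p = 0.909), and passed no threshold either way; the cause was not tested. The stricter threshold by score left 2537 of the 5074 combined regions, 10.7% of the arms in place of 16.5%, and 1.82% of the heterochromatin scaffolds in place of 4.45%, by its own construction. Merging regions closer than 1 kb gave 16.8% of the arms, since the gaps then count as covered. Replacing the combined list by a single replicate gave 14.9% to 15.2% of the arms, 3.44% to 3.60% of the scaffolds and a rho of score and width of 0.580 to 0.589 in place of 0.554; the cause was not tested. The centromeric ends differed from the rotations by -4.90 percentage points (permutation p = 0.038) when 1 Mb was taken in place of 2 Mb (-2.44, permutation p = 0.154); the cause was not tested. The settings for depleted regions, arm ends, windows, scaffolds, chromosome 4, unplaced sequence, spacing and the 10 score groups, and the use of a single replicate in place of the combined list for the number of regions, the covered share and the rho of score and width, were chosen after seeing the data. With reciprocal overlap of 50%, 93.2% of replicate 1 and 94.3% of replicate 2 regions were shared, and the shared regions scored 0.58 and 0.78 above the unshared ones in place of 0.88 and 0.95. The limit of 500 bp removed no region, so its 9 values test nothing and are left out of these numbers. Other settings for start sites, gene features, gene lists, whole-gene regions and X-linked genes, set before the data were examined, were not run, since the gene table is of release 6. No paired analysis was possible because no region lists of the input libraries are analysed here. Depth is unknown, so its effect on the number of called regions cannot be separated from that of the combined call.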

Other observations

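The tests of spacing were chosen after the result was seen. Enriched regions were crowded together and left long empty stretches between the groups. Over the 5 large arms the median gap between neighbouring regions was 6.43 kb in the combined list, 6.55 kb in replicate 1 and 6.71 kb in replicate 2, against 14.3, 14.9 and 15.1 kb with the same number of regions placed at random. Gaps of at least 100 kb numbered 211, 226 and 226, while 1000 random placements gave at most 65, 73 and 75 (one-sided permutation p = 0.001 in each list, the smallest they can give). Merging combined regions closer than 1 kb left 211 such gaps. The median gap after merging is not given. The shortest gap of the combined list was 0.001 kb, so stretches called as several regions may add to the short gaps. Stretches of at least 100 kb with no enriched region in any of the 3 lists numbered 210, of which 55 lay on 3R, 45 on 2L, 42 on X, 39 on 3L and 29 on 2R. The longest was on 3R at 2486773 to 2891691 (404.9 kb), followed by X at 20530911 to 20898009 (367.1 kb), 3R at 1835362 to 2169983 (334.6 kb), 3R at 23815190 to 24142691 (327.5 kb) and 2L at 13906877 to 14232946 (326.1 kb). The fourth of these is followed directly by a 24.8 kb enriched region, 24142692 to 24167530, which scored 2.15 in the combined list and 2.08 and 2.21 in the replicate lists. Unsequenced or repeated stretches of the assembly were not taken into account.

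The cells are labelled female, yet the YHet scaffold held 7 enriched regions in the combined list, 4 in replicate 1 and 5 in replicate 2. Both replicates overlapped 3 of the 7. These lay at 295066 to 297980 with a combined score of 1.38, at 304272 to 308118 with 2.57 and at 319962 to 322188 with 1.70. In the lists of replicates 1 and 2 the second of these scored 3.13 and 2.16. A score that another region of the same list holds exactly, which a ratio of small numbers would give, was carried by 1 of the 7 YHet regions in the combined list, 1 of 4 in replicate 1 and 3 of 5 in replicate 2, against 184 of 5074, 190 of 4874 and 168 of 4822 regions over all sequences of these lists. Such scores were not particular to YHet: 48, 21 and 19 of them lay off the 6 arms. There the lists held 146, 110 and 113 regions on all scaffolds and 98, 56 and 57 on U. The shares on YHet were not tested.

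The hypothesis that neighbouring regions carry alike scores, as domains of high and low polymerase would give, was tested with a bound set before the result was seen. Across 4771 pairs of adjacent regions on the large arms of the combined list, Spearman's rho was -0.012 (one-sided permutation p = 0.787), and it was -0.024 and -0.017 in the replicates. No likeness of score between neighbours was detected, although the regions crowd together in position.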
